A study of Mus musculus with 12 samples.

How the data were processed

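RNA from mammary tumours of mice was measured on 12 Illumina bead arrays, which carry one-colour probes read by fluorescence. Per the labels, the animals were female mice of the FVB strain carrying the MMTV-neu transgene, which drives the HER2/neu oncogene in the mammary gland, and tumours were taken at 35 weeks. Per the labels, the 4 labelled groups had 3 arrays each. These were wild-type for sphingosine kinase 1 (SphK1) from the intercross of the transgenic and knockout (KO) mice, single-transgenic controls that were also SphK1 wild-type, heterozygous KO and homozygous KO. The 2 SphK1 wild-type groups together formed the reference, as the submitters' design text treats them. Nothing in the labels says that the tumours of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

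The authors deposited a raw table of mean bead intensity on a linear scale for 45281 probes, with no background subtraction visible in the values. Beside each intensity the authors deposited a detection p-value, which compares the probe with the array's negative controls. Per the labels, RNA was column-purified, amplified and biotin-labelled as cRNA before hybridisation. The authors also deposited a processed table with 30819 gene symbols. Its values were log2 intensities as deposited, established by setting each column against the raw intensities of the same array: the median absolute difference from the log2 of quantile-normalised means per symbol was 0.00196, 87.7% of values lay within 0.01, and the lowest correlation over symbols was 0.9999. The columns of that table had medians between 6.80 and 6.81, genes were not centred, and no direction is involved because each array has a single colour. The submitters' processing notes name Partek and GCRMA without versions. The steps in which they were used are not given in the sources used here.

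The raw intensities were background-corrected and quantile-normalised with neqc in limma 3.58.1 under R 4.3.3, which adds an offset of 16, and all tests used the resulting log2 values. This normalisation compresses differences near background, so log2 differences of dim probes understate the change. A probe was tested if its detection p-value was under 0.01 on at least 3 of the 12 arrays, which kept 15892 probes. Gene symbols were updated through a RefSeq gene table of assembly GRCm38.p6, which was used only for names and gene order and from which no coordinates are given. Of the probes, 27760 had a current symbol, 8088 were renamed through a synonym and 9433 kept the symbol in the file. A spreadsheet had turned 47 symbols into dates or numbers, and 36 of these were restored from the probe description. For each symbol the detected probe with the highest mean was kept, which gave 11229 genes, of which 7822 had 1 detected probe and 3407 had more. No per-sample column was left without a sample (0 columns).

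Arrays were compared before averaging. If 2 arrays hold the same RNA, their difference at one probe of a gene should not predict their difference at another probe of that gene. Over 1249 genes with such probe pairs, heterozygous KO arrays 1 and 2 gave a correlation of 0.0228 (permutation p = 0.218), and 2 of 12681 probes detected on all arrays differed by over 2-fold. By this comparison their difference could not be told from measurement noise, whose size was not measured, and they were counted as 1 sample, called heterozygous KO tumour 1-2. The SD of their difference was 0.184. Control arrays 1 and 2 gave a correlation of 0.303 (permutation p = 0.000999, the smallest that 1000 permutations can give) with 5 probes over 2-fold and an SD of 0.178, and were kept as separate samples. The other 64 pairs gave correlations of 0.648 to 0.911 and 114 to 1174 probes over 2-fold. The averaging left 11 samples: 6 SphK1 wild-type, 2 heterozygous KO and 3 homozygous KO. This step was chosen after seeing the data.

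Linear models were fitted with lmFit and eBayes in limma, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. All samples entered one model of the 3 SphK1 genotypes, so that groups of 2 to 3 samples shared one estimate of the spread. Intercross wild-type and control tumours were compared in a model of the 4 labelled groups. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists, and beside it with camera at an estimated correlation and with fry. Of 29 lists, 28 had the 5 tested members that were required. List scores per tumour are means of the members' log2 values, each centred on its mean over the 11 samples. Where a probe was not detected in any sample of a group, the fold is a lower bound. It sets the mean of the brighter group against the mean of, per array, the lowest signal among detected probes or the probe's own signal, whichever was higher. The model, the lists, the reference, the rule for named genes and most alternatives were fixed before the data were examined.

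The rule for named genes took Sphk1 and Sphk2, then up to 12 genes with a symbol per direction with the largest difference among those that passed (5 per direction in the comparisons of both KO groups and of both reference groups). Missing places were filled with genes at least 2-fold different with the smallest unadjusted p, which did not pass the test. List members were named as examples, up to 4 with the smallest p. Clone-named and predicted transcripts were passed over. The few that passed the test are named all the same and were chosen after their values were seen.

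The fixed lists covered sphingolipid metabolism and S1P signalling, genes beside Sphk1 on chromosome 11, ERBB receptors, cell cycle, apoptosis, luminal, basal and milk-secretory epithelium, tight junctions, epithelial-mesenchymal transition, and markers of adipocytes, fibroblasts, endothelium, macrophages, T and NK cells, B cells, neutrophils, skeletal muscle and red blood cells. They also covered NF-kB and COX-2 signalling, the interferon response, antigen presentation, hypoxia, cholesterol synthesis, immediate early genes, the unfolded protein response, ribosomal proteins and oxidative phosphorylation.

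The tests were checked on simulated data in which 200 of 11229 genes were changed, with 10 simulations per comparison. With 3 against 6 samples, 74.3% of 2-fold and 91.8% of 4-fold changes were found and 4.65% of calls were false. With 2 against 6 samples these shares were 64.8%, 88.4% and 4.73%. With no change built in, 1 and 0 genes were called. Noise was drawn as normal and independent between genes with the fitted spread, so these shares may not hold for the real tumours. A list of 38 members raised by 0.5 on the log2 scale was found in 10 of 10 simulations with 0 false list calls, in genes simulated as independent, which real genes are not. The number of arrays limits the precision.

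Alternatives covered no background correction, median scaling, the authors' processed values, other filters on dim probes, every probe on its own, a model of the 4 groups, each reference group alone, only the groups compared, array weights, an intensity trend with a robust prior, the first 6 against the last 6 arrays in the labels' running numbers as a block, a linear term for null alleles, other set tests and each replicate left out. Values within the last 6 arrays, with arrays as samples (2 per SphK1 genotype), are given beside the results and were computed after the data were seen. There were 3 alternatives chosen after seeing the data: 12 arrays each counted as a sample, control 1 and 2 counted as 1 sample, and heterozygous KO tumour 1-2 with homozygous KO tumour 2 left out. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.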

Results

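Gene expression was profiled in MMTV-neu mammary tumours that differed in SphK1, the kinase that makes the lipid mediator sphingosine 1-phosphate. The design asks how loss of 1 or both SphK1 alleles changes tumours driven by HER2/neu. After heterozygous KO arrays 1 and 2, whose difference could not be told from measurement noise by a comparison of probes, were counted as 1 sample, there were 6 SphK1 wild-type tumours (3 intercross wild-type and 3 single-transgenic controls), 2 labelled heterozygous KO and 3 labelled homozygous KO. Between 14135 and 15478 of 45281 probes were detected per array (31.2% to 34.2%), and the median raw intensity ran from 106 to 118. The lowest raw intensity of an array was 54.1 to 58.2 in the first 6 arrays by the labels' running numbers and 58.7 to 66.6 in the last 6. Principal components were computed on the 12 arrays before averaging, so heterozygous KO tumour 1-2 entered as 2 arrays and weighed more than the others. The first component held 44.1% of the variance. This component set heterozygous KO tumour 1-2 (47.5, the mean of its arrays) and homozygous KO tumour 2 (49.9) apart from the other 9 tumours (-24.7 to 8.32).

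The targeted gene did not separate the genotypes. Sphk1 averaged 9.64 ± 1.03 on the log2 scale in SphK1 wild-type tumours (SD, n = 6), 9.91 ± 1.87 in tumours labelled heterozygous KO (n = 2) and 9.63 ± 0.48 in tumours labelled homozygous KO (n = 3). The difference from wild-type was -0.01 (SE 0.67, limma adjusted p = 0.998) in the tumours labelled homozygous KO and 0.27 (SE 0.78, adjusted p = 0.960) in those labelled heterozygous KO. Of 3 Sphk1 probes, 1 was detected, on all 12 arrays. Where that probe lies relative to the deleted part of the gene is not known here, so its signal checks nothing about the labels, and genotypes are given as labelled throughout. Single tumours lay high, with 11.48 in wild-type 2 and 11.23 in heterozygous KO 1-2 against 8.42 to 10.10 in the others. Leaving out wild-type 2 turned the homozygous difference to 0.35, and leaving out heterozygous KO 1-2 turned the heterozygous one to -1.05. The differences were 0.91 (SE 0.91) and 0.92 (SE 0.91) within the last 6 arrays by running number, where control 3 and wild-type 3 alone are the reference, so that single tumours weigh heavily in all values given for these arrays. The related kinase Sphk2 differed by -0.20 (SE 0.14, adjusted p = 0.725) and -0.34 (SE 0.16, adjusted p = 0.668). The list of sphingolipid metabolism and S1P signalling, with 27 measured members, was not shifted in tumours labelled homozygous KO (median -0.03, camera adjusted p = 0.617) or heterozygous KO (median -0.04, adjusted p = 0.913). In it Degs1, the dihydroceramide desaturase, differed by 0.36 and Sgpl1, the lyase that degrades sphingosine 1-phosphate, by -0.25 in the tumours labelled homozygous KO. Neither passed (0 of 27 over all genes and 0 adjusted over the list alone).

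Tumours labelled homozygous KO differed from SphK1 wild-type tumours in few transcripts, all higher, and 4 of them lie near Sphk1 in the genome. St6galnac2, a sialyltransferase of the Golgi, rose 7.03-fold, from 10.41 ± 0.32 to 13.23 ± 0.78 (SD, n = 6 and 3; log2 difference 2.81, SE 0.37, limma adjusted p = 0.0220). Snhg16, a host gene of small nucleolar RNAs, rose 2.93-fold (log2 difference 1.55, SE 0.19, adjusted p = 0.0156), and Exoc7, a subunit of the exocyst complex that tethers secretory vesicles, rose 2.53-fold (1.34, SE 0.13, adjusted p = 0.00192). The clone-named transcript BC018473 was not detected in any wild-type tumour and was at least 34.0-fold higher in those labelled homozygous KO (means 4.95 and 11.44, adjusted p = 7.19e-05). E430014K09Rik, whose place in the genome is not known here, was likewise undetected in all 6 wild-type tumours and at least 364-fold higher (means 4.90 and 14.86, adjusted p = 4.20e-09).

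Of the remaining genes that passed, E430031D18Rik rose 4.17-fold (log2 difference 2.06, SE 0.20, adjusted p = 0.00192). BC032265 was undetected in wild-type tumours and at least 1.26-fold higher (adjusted p = 0.000413). Meiob, a gene of meiotic recombination, was detected in 2 of 3 tumours labelled homozygous KO and 0 of 6 wild-type tumours, so no fold is given. Its log2 difference of 1.18 (SE 0.15, limma adjusted p = 0.0156) was taken against background signal in wild-type tumours. Within the last 6 arrays, where 1 gene passed (E430014K09Rik), Exoc7 differed by 1.43, St6galnac2 by 2.71 and Snhg16 by 1.59, and none of these 3 passed (adjusted p from 0.753 to 0.982). In all, 8 genes rose and 0 fell among 11229, while 905 had an unadjusted p under 0.05 (404 higher and 501 lower), against 561 expected by chance. BC018473, BC032265, E430014K09Rik and E430031D18Rik are clone names outside the naming rule and were chosen after their values were seen. Probes disagreed in 2 genes: a second St6galnac2 probe differed by -0.06, and the 3 Snhg16 probes differed by 1.55, -0.02 and 1.90. Each of the other genes that passed had 1 detected probe, so agreement between probes could not be checked for them. The count depended on the tumours included: it was 5 with intercross wild-type tumours alone as the reference and 5 without wild-type 1, control 2, control 3 or homozygous KO 3. It was 120 (91 higher, 29 lower) with heterozygous KO 1-2 and homozygous KO 2 left out, when all 8 genes were among the 120. With their direction kept, single tumours also decided 3 of the calls. St6galnac2 lost its call without wild-type 1 or 3, any control, homozygous KO 1 or 3 (adjusted p up to 0.192). Snhg16 lost it without wild-type 1, any control, homozygous KO 2 or 3 (up to 0.152), and Meiob without wild-type 1, control 2 or 3, homozygous KO 2 or 3 (up to 0.166).

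**Figure D1:**
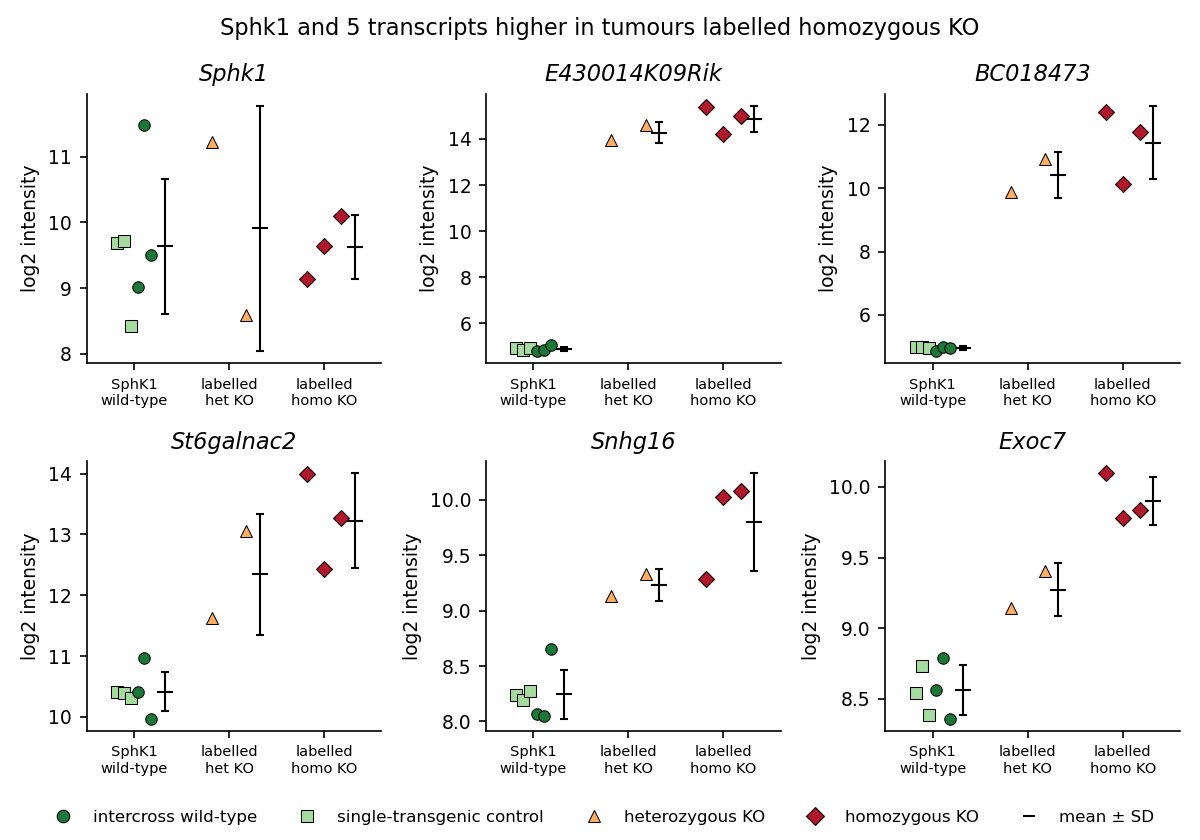
Log2 intensity (vertical axis) of Sphk1 and of 5 transcripts that rose in tumours labelled homozygous KO, by genotype, with a point per tumour and mean ± SD. Sphk1 overlaps between genotypes (means 9.64, 9.91 and 9.63), while E430014K09Rik is near 4.90 in all wild-type tumours and averages 14.27 and 14.86 in those labelled heterozygous and homozygous KO.

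The position of these genes was compared with that of all genes placed in the reference. Of the 8 genes that rose, 5 had a known place, and 4 of these (80%) lay within 20 measured genes of Sphk1 on either side, against 0.421% of the 9746 placed genes (Fisher's exact p = 1.34e-09, two-sided). These were Exoc7, the 3rd measured gene on one side, and Snhg16, St6galnac2 and BC018473, the 4th to 6th on the other. The measured genes between them and Sphk1 did not pass. Of the 41 genes in the window, 6 had an unadjusted limma p under 0.05, against 7.93% of all placed genes. In the array file Meiob is on chromosome 17, and BC032265, which has no place in the reference, is on chromosome 11. The window of 20 genes was chosen after seeing the data, whereas the list of genes beside Sphk1 was fixed before. In that list of 30 measured members, 2 rose over all genes and 3 changed when adjusted over the list alone: Exoc7 and St6galnac2 rose, and Trim47, a ubiquitin ligase of the TRIM family, fell by 0.56 (SE 0.11, adjusted p over all genes 0.168). Its members did not move one way, with a median of -0.04 and a mean of 0.10, which differ in sign (camera adjusted p = 0.982). Fry's mixed test, which a few strong members can carry, gave an adjusted p of 7.08e-07, and 5 of 30 had an unadjusted p under 0.05. Timp2, an inhibitor of matrix metalloproteinases in the same list, differed by -1.12 (SE 0.41, adjusted p = 0.549).

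**Figure D2:**
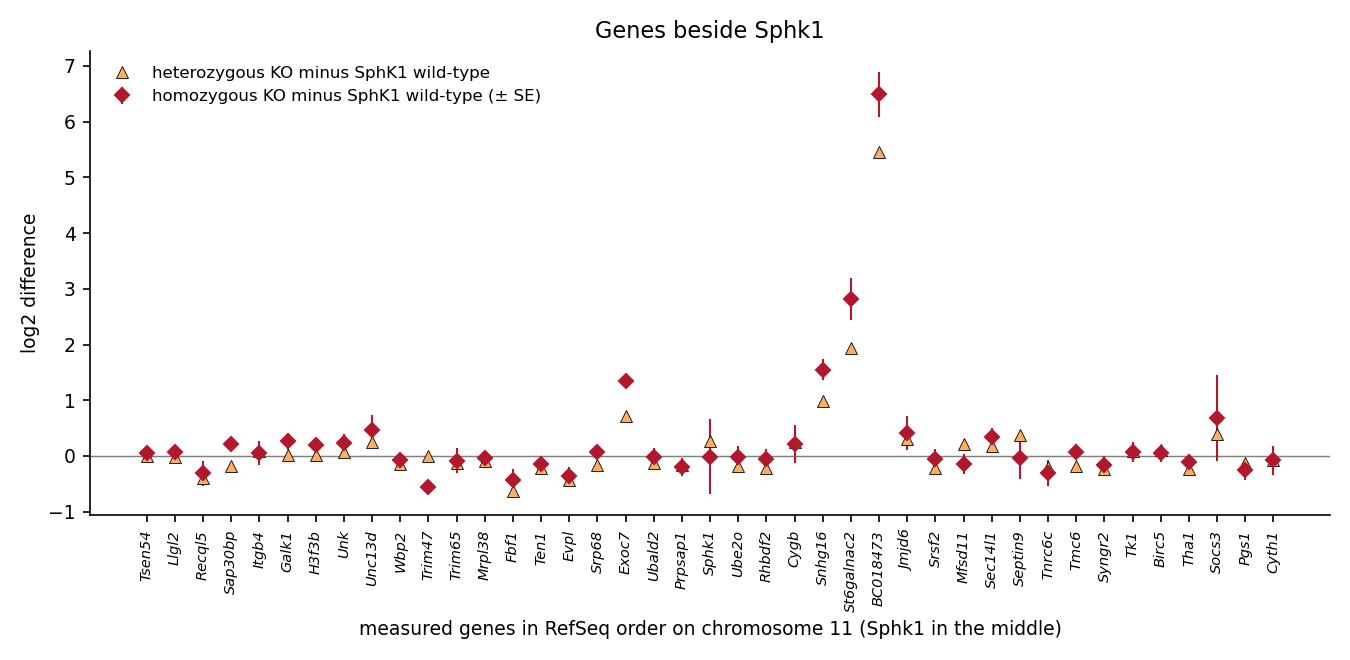
Log2 difference from SphK1 wild-type tumours (vertical axis) of the 41 measured genes around Sphk1 in genome order (horizontal axis), for tumours labelled homozygous KO with SE and for those labelled heterozygous KO. BC018473 (6.49 and 5.46, from a wild-type level not above background), St6galnac2 (2.81 and 1.93), Snhg16 (1.55 and 0.99) and Exoc7 (1.34 and 0.71) stand out, and Sphk1 itself lies at -0.01 and 0.27.

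Among the fixed lists, the interferon response was higher in tumours labelled homozygous KO. All 28 measured members had higher means than in wild-type tumours, with a median log2 difference of 1.01 (camera adjusted p = 3.20e-11), and adjusted p = 0.952 with an estimated correlation. None passed over all genes (0 in limma, 9 at an unadjusted p under 0.05), and 1 rose when adjusted over the list alone: Ifitm3, a membrane protein that restricts virus entry (1.96, SE 0.41). Bst2, which tethers budding viruses, differed by 1.51 (SE 0.50), Rsad2, the antiviral enzyme viperin, by 1.40 (SE 0.56) and Ifit3 by 1.99 (SE 0.81). The scores were 1.17 and 1.32 in homozygous KO 1 and 3 but -1.07 in homozygous KO 2, which lay below all 6 wild-type tumours (-1.02 to -0.17). The T and NK cell scores ran alike in 4 of the 5 KO tumours, with 0.37 and 0.25 in homozygous KO 1 and 3, -0.61 in homozygous KO 2 and 0.57 in heterozygous KO 3, whose interferon score was the highest (1.66). Heterozygous KO 1-2 did not follow this, with an interferon score of 0.42, above all wild-type tumours, and a T and NK cell score of -0.10, inside their range (-0.20 to 0.06). With the first and last 6 arrays as a block, the median was 1.03 and the list still passed. Within the last 6 arrays, which hold 2 of each SphK1 genotype, it was 0.44 (25 of 28 higher, adjusted p = 0.0251), while the first 6 hold 1 homozygous KO and 1 heterozygous KO array, too few for values of their own. Without homozygous KO 3 the median was 0.59, and without homozygous KO 2 it was 1.92. Antigen presentation was also higher (median 0.42 over 16 members, adjusted p = 0.0357, within the last 6 arrays 0.17 and 0.410, and adjusted p = 0.952 with an estimated correlation), with the peptide transporter subunits Tap1 at 1.08 and Tap2 at 0.61. None of its members passed (0 over all genes, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05), and the call was lost without homozygous KO 1 or 3, control 1 or 2, or wild-type 3 (adjusted p up to 0.819).

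The other called lists moved less in the tumours labelled homozygous KO, and for each the adjusted p was 0.952 with an estimated correlation. Hypoxia and glycolysis had a median of 0.29 over 25 members (camera adjusted p = 0.0108), with Egln1, an oxygen-sensing prolyl hydroxylase, at 0.97, Vegfa, the vascular growth factor, at 0.93 and the glycolytic enzyme Aldoa at 0.44. With the array block its median was 0.12 (adjusted p = 0.442). Oxidative phosphorylation had a median of 0.05 over 36 members (adjusted p = 0.0264), with Sdhd at 0.27 and Ndufv2 at 0.18. Milk proteins had a median of -0.28 over 22 members (adjusted p = 0.0418), with Lalba, alpha-lactalbumin, at -1.07 and Lao1 at -1.97. None of these 3 lists had a member that passed over all genes or adjusted over the list alone (0 and 0 in each). Cholesterol and fatty acid synthesis had a median of -0.14 over 23 members (adjusted p = 0.0418). None passed over all genes (0), and 2 fell when adjusted over the list alone: Elovl6, a fatty acid elongase, fell by 0.95 (SE 0.21) and Stard4, a cholesterol carrier, fell by 0.66 (SE 0.15), while Srebf2, a regulator of cholesterol synthesis, differed by -0.49 (SE 0.18). With the array block, milk proteins (adjusted p = 0.126) and cholesterol synthesis (adjusted p = 0.0683) no longer passed. Medians within the last 6 arrays were 0.18 for hypoxia (adjusted p = 0.144), 0.09 for oxidative phosphorylation (0.144), -0.38 for milk proteins (0.00818) and -0.19 for cholesterol synthesis (0.0393). Calls were also lost without homozygous KO 2 or 3 for hypoxia (adjusted p up to 0.411), wild-type 2 or homozygous KO 3 for oxidative phosphorylation (up to 0.292), homozygous KO 2 or 3, wild-type 2 or any control for milk proteins (up to 0.346). The same held without homozygous KO 2, wild-type 2, control 2 or 3 for cholesterol synthesis (up to 0.667).

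Lists that were not called included tight junctions (median -0.10 over 19 members, camera adjusted p = 0.120), where Cldn2, a pore-forming claudin, differed by -2.03 (SE 0.77) and F11r, a junctional adhesion molecule, by -0.36. Cell cycle was not called either (median -0.04 over 33 members, adjusted p = 0.982), where the proliferation marker Mki67 differed by -0.58 and Ube2c by 0.37. Within the last 6 arrays cell cycle genes were higher in both KO groups (homozygous median 0.22, 29 of 33 higher, adjusted p = 0.00116; heterozygous 0.19, 28 of 33, adjusted p = 0.000694). This rested on wild-type 3 (score -0.38), since control 3 (0.09) lay among the KO tumours there (-0.02 to 0.14). Lists called there but not over all tumours in these comparisons also included skeletal muscle (-2.30 and -2.12), where control 3 alone was high (4.25, against -0.92 in wild-type 3), and red blood cells (-1.35 and -0.96), where both reference tumours were high (1.18 and 0.94). In homozygous KO they included adipocytes (-0.36), lowest in homozygous KO 3 (-0.67), and B cells (-0.67), lowest in homozygous KO 2 (-0.91). ERBB receptors, ligands and adaptors were not shifted (median -0.04 over 14 members, adjusted p = 0.879). In the mouse Erbb2 probe, whose match to the transgene is not known here, levels were 9.48 ± 0.18 in wild-type tumours, 9.32 ± 0.27 in those labelled heterozygous and 9.43 ± 0.28 in those labelled homozygous KO.

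Genes taken by the naming rule at 2-fold or more that did not pass included interferon-inducible Ifitm1 (1.40, SE 0.22, adjusted p = 0.0676) and Gvin1 (1.68, SE 0.28), while Plac8 was at 1.46, Vmn1r65 at 1.40, Nuak2 at 1.11 and Cpeb2 at 1.02. C1qtnf9 was undetected in wild-type tumours and at least 1.55-fold higher. On the lower side, Sectm1a was undetected in tumours labelled homozygous KO and at least 1.67-fold lower (adjusted p = 0.0602), Scnn1b, a subunit of the epithelial sodium channel, differed by -1.10 (SE 0.18, adjusted p = 0.0676), and Cd1d1, which presents lipid antigens, by -1.75 (SE 0.37, adjusted p = 0.256). Eln, the elastin gene, differed by -1.19, Bicdl1 by -1.29, Btbd11 by -1.29, Sdr16c5 by -2.59 and Kcng2 by -2.47. Pcdhb3, Cda and Pcolce2 were undetected in these tumours and at least 2.04-fold, 1.80-fold and 1.06-fold lower. Pisd-ps2 was also undetected there, with no fold given.

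Tumours labelled heterozygous KO shared the 2 largest of these changes and were also higher in several immune-related genes. E430014K09Rik was at least 242-fold higher (adjusted p = 3.40e-08), BC018473 at least 16.6-fold higher (adjusted p = 0.00159) and Meiob at least 1.46-fold higher (adjusted p = 0.00384) than in wild-type tumours, where none was detected. Plac8 rose 9.99-fold, from 6.92 ± 0.45 to 10.24 ± 0.32 (SD, n = 6 and 2; log2 difference 3.32, SE 0.46, limma adjusted p = 0.0381). The interferon-inducible genes Ifi202b and Ifitm1 rose 4.60-fold (2.20, SE 0.27, adjusted p = 0.0265) and 3.39-fold (1.76, SE 0.26, adjusted p = 0.0460), and Irf8, a transcription factor of myeloid cells, rose 1.85-fold (0.89, SE 0.13, adjusted p = 0.0460). LOC100044439, a predicted transcript chosen after its values were seen, was at least 4.09-fold higher (adjusted p = 0.0357).

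In the same comparison Adra2c, an alpha-2 adrenergic receptor, fell by 1.17 on the log2 scale (SE 0.15, adjusted p = 0.0355) and Slc20a1, a phosphate transporter, fell by 1.04 (SE 0.15, adjusted p = 0.0460). In all, 8 genes rose and 2 fell, and 890 had an unadjusted p under 0.05. Beside Sphk1, St6galnac2 (1.93, SE 0.43) and Exoc7 (0.71, SE 0.15) rose when adjusted over the list alone, while Snhg16, which is not in the list, differed by 0.99. Over all genes 0 of that list passed. Of the 8 placed genes that passed, 1 (12.5%), BC018473, lay within 20 measured genes of Sphk1 (Fisher's exact p = 0.0332, two-sided). The window was chosen after the data were seen, and BC018473 also rose in homozygous KO against the same reference tumours. This p is therefore no separate test of position. The count was 0 among probes detected on all 12 arrays, 4 with the array block, 3 without heterozygous KO 1-2, wild-type 1, control 2 or control 3, 4 without control 1 or wild-type 3, 5 without homozygous KO 1, and 6 with array 2 alone for heterozygous KO 1-2. It was 18 without homozygous KO 2, and 81 with both tumours that stood apart left out. Plac8, Ifi202b, Ifitm1, Irf8, Adra2c, Slc20a1 and LOC100044439 each lost the call, with the direction kept, without any of heterozygous KO 1-2 or 3, wild-type 1, control 2 or control 3 (adjusted p up to 0.349, 0.155, 0.349, 0.444, 0.321, 0.433 and 0.349), and some without further tumours. The arm has 2 samples, so leaving one out assumes that the lone sample varies like the other groups.

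The lists called in tumours labelled heterozygous KO included interferon response, macrophages, endothelium and antigen presentation, while T and NK cells and B cells were not called. Interferon response genes had a median of 1.59 (28 of 28 higher, camera adjusted p = 2.32e-21, and adjusted p = 0.482 with an estimated correlation). The median was 0.92 without heterozygous KO 3. Over all genes 0 passed, and 15 rose when adjusted over the list alone. Among these were Ifitm3 (2.34, SE 0.47), Ifit3 (3.18, SE 0.94), Ifit2 (1.90, SE 0.49), Bst2 (1.94, SE 0.58) and Oas2, a sensor of double-stranded RNA (3.91, SE 1.24). Macrophage and monocyte markers had a median of 1.05 (19 of 21 higher, adjusted p = 4.07e-17, and adjusted p = 0.459 with an estimated correlation), and 16 rose when adjusted over the list alone against 0 over all genes. The macrophage score was 1.23 in heterozygous KO 1-2 but 0.14 in heterozygous KO 3, below wild-type 2 (0.18), and the median without heterozygous KO 1-2 was 0.51 (adjusted p = 7.10e-05). Among the members that rose were the lipid receptor Trem2 (1.19, SE 0.20), its signalling adaptor Tyrobp (1.10, SE 0.22) and the complement components C1qa (1.11) and C1qb (1.08). Endothelial markers had a median of 0.61 (16 of 16 higher, adjusted p = 3.04e-10, and adjusted p = 0.459 with an estimated correlation), and 4 rose when adjusted over the list alone against 0 over all genes. Among them were Flt1, a receptor of vascular growth factors (0.95, SE 0.22), and Egfl7 (0.90, SE 0.23). Antigen presentation had a median of 0.86 (16 of 16 higher, adjusted p = 6.09e-07, and adjusted p = 0.482 with an estimated correlation), with the class II genes H2-Ab1 at 1.91 and H2-DMa at 1.25. None of its members passed (0 over all genes, 0 adjusted over the list alone), and its call was lost without heterozygous KO 3 (median 0.28, adjusted p = 0.182). In the last 6 arrays alone, 1 gene (E430014K09Rik) passed, and the medians were 1.46 for interferon response, 1.04 for macrophages, 0.35 for endothelium and 0.80 for antigen presentation (adjusted p = 4.55e-13, 8.88e-17, 0.000330 and 1.74e-06).

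Markers of other compartments also differed between the samples labelled heterozygous KO. Fibroblast and extracellular matrix genes had a median of 0.60 (25 of 26 higher, camera adjusted p = 0.00149, and adjusted p = 0.694 with an estimated correlation), but the scores were 2.00 in heterozygous KO 1-2 and -0.80 in heterozygous KO 3. Without heterozygous KO 1-2 the median turned to -0.66, and the collagen gene Col1a2, detected in 1 of these 2 and 1 of the 6 wild-type tumours, went from 1.15 (SE 0.74) to -0.66. Basal and myoepithelial markers had a median of 0.51 (adjusted p = 0.0216, and adjusted p = 0.694 with an estimated correlation), which turned to -0.85 without that tumour, with Cav1 at 1.30 and the intermediate filament gene Vim at 1.43. Genes of epithelial-mesenchymal transition had a median of 0.76 (adjusted p = 0.00149, and adjusted p = 0.577 with an estimated correlation), with the transcription factors Snai1 at 0.98 and Zeb1 at 0.76, and the median was 0.0075 without that tumour. Neutrophil markers had a median of 0.39 (adjusted p = 0.0269, and adjusted p = 0.577 with an estimated correlation), with Clec4d at 1.64, and -0.08 without it. The basal call was also lost without wild-type 3, and the neutrophil call without wild-type 1 or 3 (medians 0.35, 0.40 and 0.38). The last 6 arrays alone gave medians of 0.68 for fibroblasts, 0.86 for basal markers, 0.70 for epithelial-mesenchymal transition and 0.31 for neutrophils (adjusted p = 0.00804, 0.0388, 0.0388 and 0.154). For these 4 lists 0 members passed over all genes and 0 adjusted over the list alone.

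**Figure D3:**
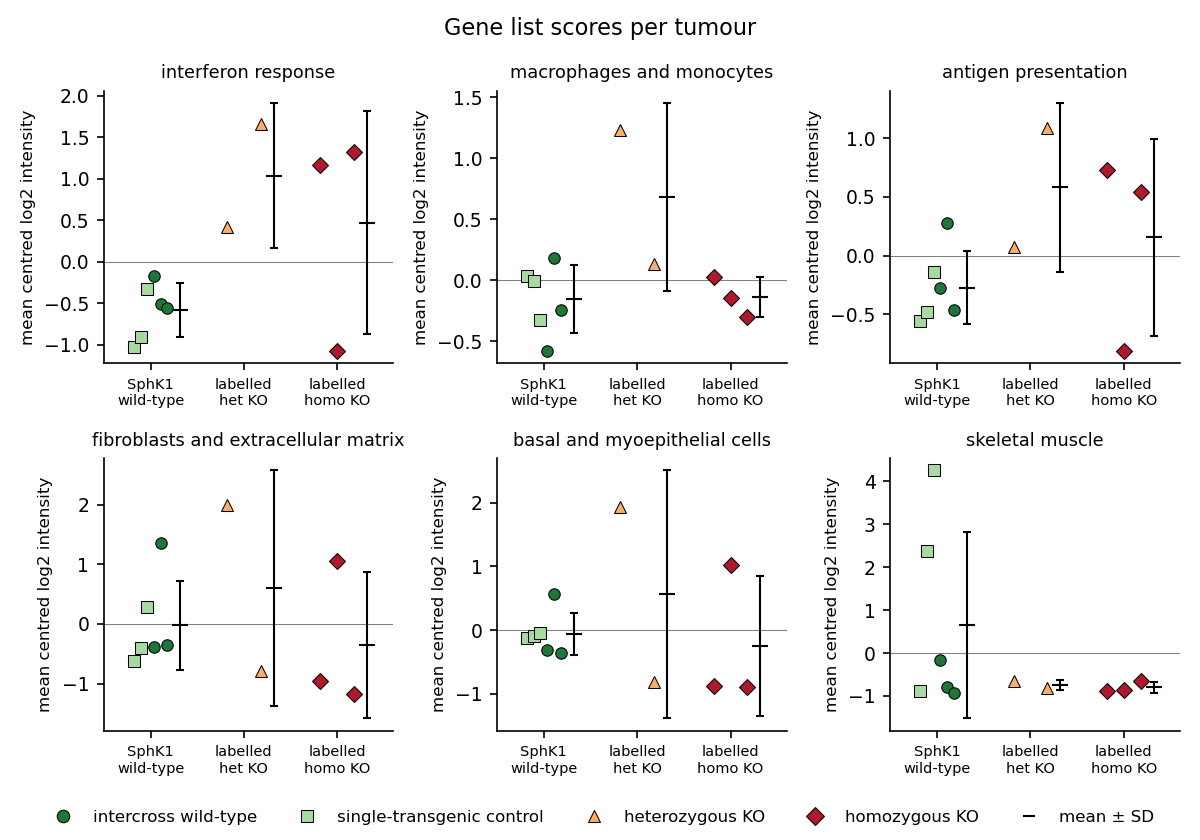
Score of 6 gene lists per tumour (vertical axis, mean log2 value of the members after centring each over the 11 samples), by genotype, with mean ± SD. Interferon scores of homozygous KO 1 and 3 (1.17 and 1.32) lie above all wild-type tumours and that of homozygous KO 2 (-1.07) below them, fibroblast scores of heterozygous KO 1-2 and 3 lie at 2.00 and -0.80, and skeletal muscle scores of control 2 and 3 reach 2.38 and 4.25.

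Smaller shifts in the tumours labelled heterozygous KO were in cholesterol and fatty acid synthesis (median -0.13, camera adjusted p = 0.0167, and adjusted p = 0.617 with an estimated correlation), with Elovl6 at -0.84 and Stard4 at -0.57. Oxidative phosphorylation was higher (median 0.06, adjusted p = 0.0167, and adjusted p = 0.482 with an estimated correlation), with Cox5a at 0.19. The unfolded protein response had a median of 0.10 (adjusted p = 0.0361, and adjusted p = 0.482 with an estimated correlation), with the endoplasmic reticulum chaperones Sdf2l1 at 0.55 and Pdia6 at 0.53. Hypoxia and glycolysis had a median of 0.27 (adjusted p = 0.0361, and adjusted p = 0.848 with an estimated correlation), with Aldoa at 0.51, and its median was -0.08 with the array block. These medians within the last 6 arrays were -0.20, 0.05, 0.10 and -0.29 in the same order (adjusted p = 0.0333, 0.146, 0.212 and 0.0508). No member of these 4 lists passed (0 over all genes, 0 adjusted over the list alone). Each of the 4 lost its call without heterozygous KO 1-2. The call was also lost for cholesterol synthesis without control 3, oxidative phosphorylation without heterozygous KO 3, the unfolded protein response without heterozygous KO 3 or wild-type 1, and hypoxia without wild-type 1 or 2, control 1 or 2, or homozygous KO 3 (adjusted p up to 0.385, 0.182, 0.234 and 0.747).

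By the naming rule, genes that did not pass in this comparison included Ifi207 (1.38, adjusted p = 0.0604), Gvin1 (2.03), Cd52, a surface protein of leukocytes (1.14), Tmem106a (1.13) and Prune2 (1.47), and P2ry14, which was undetected in wild-type tumours and at least 2.24-fold higher. On the lower side were the corepressor Tle2 (-1.30, adjusted p = 0.0604), Meis1, a homeobox factor (-1.79), Psg23 (-1.45), Tlcd4 (-1.08), Gng7 (-1.02) and Scnn1b (-1.01). Bicdl1 and Cda were undetected in tumours labelled heterozygous KO and at least 2.12-fold and 1.74-fold lower, and Pisd-ps2 and Gnaz were undetected there with no fold given.

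Set directly against each other, tumours labelled homozygous and heterozygous KO did not differ in any gene that passed limma's test (0 of 11229, smallest adjusted p = 0.433), while 379 genes had an unadjusted p under 0.05 against 561 expected by chance. By the naming rule, Vmn1r65 was undetected in the heterozygous and at least 2.09-fold higher in the homozygous tumours. Otx1 differed by 2.61 (SE 0.90), Dnaaf3 by 1.62, Meis1 by 1.52 and Npr2, a natriuretic peptide receptor, by 1.20, homozygous minus heterozygous. The macrophage receptor Trem2 differed by -1.17 (SE 0.22), Ifi202b by -1.34, Prune2 by -1.32, Mxra8 by -1.57 and the iron exporter Slc40a1 by -1.12. Of the lists, 12 were lower in the homozygous tumours by camera and 0 with an estimated correlation. The strongest were macrophages (median -0.82, 21 of 21 lower, adjusted p = 5.52e-20, and adjusted p = 0.199 with an estimated correlation), endothelium (median -0.48, 15 of 16 lower, adjusted p = 9.06e-09, and adjusted p = 0.303 with an estimated correlation) and fibroblasts (median -0.88, 25 of 26 lower, adjusted p = 4.77e-08, and adjusted p = 0.611 with an estimated correlation). The fibroblast difference rested on heterozygous KO 1-2, without which its median turned to 0.36. The macrophage median was -0.39 without that tumour, and the endothelial one -0.28 without homozygous KO 3, with both still called. Of the 12 lists, only macrophages, endothelium and the unfolded protein response kept the call with each tumour of these groups left out. Adjusted over the list alone, 7 macrophage, 1 endothelial and 1 fibroblast gene fell, against 0 over all genes.

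The 2 kinds of SphK1 wild-type tumour were compared to see whether the pooled reference was one population. Skeletal muscle genes were lower in intercross wild-type than in control tumours (median -2.75, 8 of 8 lower, camera adjusted p = 2.55e-09, and adjusted p = 0.783 with an estimated correlation). The scores were 4.25 in control 3 and 2.38 in control 2, against -0.92 to -0.16 in the other 4. Over all genes 0 of them passed, and 0 adjusted over the list alone. Among genes taken by the naming rule, the sarcomere proteins Actn2 (-1.94, SE 0.67) and Pdlim3 (-1.32, SE 0.47) were on the lower side with Mns1 (-1.63), C2cd4a (-1.40) and the immediate early gene Fosb (-1.75). The class II genes Cd74 (1.66, SE 0.61) and H2-Ab1 (1.65, SE 0.62) were on the higher side with Mat1a (1.62), Rasl11b (1.54) and Cpne8 (1.30). No gene passed limma's test (0 of 11229, smallest adjusted p = 1.00), with 194 at an unadjusted p under 0.05. The other 6 of 7 called lists were cell cycle (median -0.18, adjusted p = 3.46e-06), red blood cells (-1.18, adjusted p = 0.00280), milk proteins (-0.21, adjusted p = 0.00437), interferon response (0.24, adjusted p = 0.00280), fibroblasts (0.50, adjusted p = 0.0256) and hypoxia (0.22, adjusted p = 0.0256). Each of these 6 lost its call without at least 1 tumour. Without wild-type 3 the medians were -0.015 for cell cycle and -0.12 for hypoxia, and without wild-type 2 that of fibroblasts was -0.16. Muscle kept its call, with -1.49 without control 3. With an estimated correlation 0 lists were called, and the smallest adjusted p was 0.783 with an estimated correlation.

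Differences from wild-type were compared between the genotypes over all genes. The correlation across genes, which are not independent replicates, was 0.66 and the covariance 0.0892, and 70.8% of genes had the same sign. Because both comparisons share the same 6 reference tumours, unchanged groups were also simulated 100 times. On average these gave a correlation of 0.29, a covariance of 0.0282 and 59.4% of genes with the same sign. The spread of these simulations is not given. Heterozygous KO 1-2 and homozygous KO 2 lay together on the first principal component. The simulated mean therefore cannot show that the observed correlation reflects SphK1 genotype. With the reference split, so that each comparison had its own 3 tumours, the correlations were 0.48 and 0.49 and the covariances 0.0711 and 0.0748. Without homozygous KO 2 the correlation was 0.41. Both genotypes shared 3 genes that rose, E430014K09Rik, BC018473 and Meiob, in comparisons that share the reference.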

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

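Chosen only after the result was seen were the tests of gene position in the window, of single probes, of SphK1 genotype, of array order, of poor arrays and of the share of non-epithelial cells. The tests of more distant genes, immune cell scores and other splits of the samples were chosen before.

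Among 17 genes and 16 list scores tested in the 6 SphK1 wild-type tumours, an extreme tumour lay far from the others in 3, where chance gives about 1 in 20. BC018473 was 4.86 in wild-type 1 against 4.95 in the nearest tumour, a gap of 0.689 of the range, with the transcript undetected in all 6. The score of basal and myoepithelial markers was 0.56 in wild-type 2 against -0.04 in the nearest, a gap of 0.660 of the range. The score of the unfolded protein response was -0.25 in wild-type 1 against 0.01 in the nearest, a gap of 0.726 of the range.

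Of the placed genes that rose in tumours labelled homozygous KO, 80% lay within 20 measured genes of Sphk1, against 0.421% of all placed genes. Loss of SphK1 activity acting on genes wherever they lie would not be expected to cluster them there. The Fisher's exact p of 1.34e-09 is not corrected for the choice of the window after these genes were seen. Other local causes were not tested. DNA of another strain carried with the null allele may cluster them, as a hypothesis found and tested on the same data. Whether such DNA reaches further stays open, since 9.02% of the 133 genes from the 21st to the 100th on one side and from the 21st to the last measured gene, the 73rd, on the other had an unadjusted p under 0.05 against 7.89% of the other 9572 (one-sided Fisher's exact p = 0.360). That test was first set to count against further DNA at any p of 0.05 or more, which was too loose, because the odds ratio of 1.16 has a 95% interval of 0.580 to 2.11. A sequence variant under single probes also stays open. Of the 2 genes with more than 1 detected probe, St6galnac2 and Snhg16, 0 had all probes moving the same way. In St6galnac2, 1 of 2 probes rose. In Snhg16, 2 of 3 rose, by 1.55 and 1.90, the latter detected on only 4 arrays.

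The interferon score was higher in 4 of the 5 tumours labelled KO than in any wild-type tumour and lower in the other, homozygous KO 2, than in all of them (exact two-sided permutation p = 0.0303, 5 against 6). With labels exchanged only within the first and last 6 arrays, p was 0.0600 or 0.0667, depending on the set in which heterozygous KO 1-2 was placed. This list was the strongest of 28 and was picked for that reason, so the p is not corrected for the choice, and an effect of SphK1 genotype is a hypothesis. With the macrophage and T cell scores as covariates, the difference kept 82.2% (SE 21.6) in tumours labelled homozygous KO but 55.9% (SE 28.1) in those labelled heterozygous KO, so more immune cells cannot be told apart from it. A shift between the first and last 6 arrays is excluded as the whole account: among wild-type tumours the last less the first differed by 0.21 (SE 0.30), and the shares of arrays in each set would need a shift of 3.16 for homozygous and 3.89 for heterozygous KO. An earlier test asked whether the difference kept over 50% by more than 1 SE with the sets as a term. It kept 102% (SE 58.9) and 101% (SE 44.6), but was replaced because the error in homozygous KO was 52.4% even with no term, so it could not have decided.

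Heterozygous KO 1-2 and homozygous KO 2 stood apart from the other tumours on the first principal component. By detected probes and median raw intensity, poor arrays do not account for all of this, since 2 of their 3 arrays lay inside the range of the other 9 in both. These measures do not show RNA or tissue quality, so a poor sample is not excluded. The test first asked whether any of the 3 lay outside, which heterozygous KO array 2 did (median raw intensity 118 against a highest of 117), and was rewritten after that was seen. A shift by SphK1 genotype in 1 direction is excluded as the whole account, because the other 3 tumours labelled KO lay on the opposite side of the wild-type median. No tumour labelled KO lay inside the wild-type range of -18.4 to 8.32, and whether KO tumours spread more widely was not tested. A rise of all non-epithelial cell types together was not seen in homozygous KO 2, whose T and NK cell score of -0.61 was below the lowest of the other 9 tumours (-0.20). The test cannot exclude a larger share of some of these types. The fibroblast score was 1.05 there, against -0.62 to 1.37 in wild-type tumours. In heterozygous KO 1-2, with a T and NK cell score of -0.10, a rise of all types is not excluded and may contribute.

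Other splits of the samples were compared with the real ones. For homozygous KO against wild-type tumours, 2 of the 84 splits, the real one included, gave as many genes. The real split gave 8, and the highest other gave 16. That other split set homozygous KO 2, homozygous KO 3 and wild-type 3 against the rest, samples that are all among the last 6 arrays. Chance is excluded for that count at the 0.05 level only if all samples are exchangeable. Splits within the first and last 6 arrays were not run for it. For the count of lists, 63 of the 84 gave as many (6 in the real split, 17 in the highest other), so chance is not excluded. Heterozygous KO against wild-type tumours was not split in this way, so its counts of genes and lists have no such check. For intercross wild-type against control tumours, 10 of 10 splits gave as many genes (0 in the real split, 0 in the highest other) and 7 of 10 as many lists (7 and 16), and 10 splits are too few for a share under 0.05.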

How the results depend on the processing

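Of the alternatives, those that counted 12 arrays each as a sample, counted control 1 and 2 as 1 sample, or left out heterozygous KO 1-2 with homozygous KO 2 were chosen after seeing the data. The beadchip as a block was not run, because no source used here names beadchips. No paired analysis was possible because the labels give no replicate numbers shared between groups. Signal over background limits transcripts such as Meiob and BC032265, undetected in wild-type tumours. Where a count or value moved, the cause was not tested, except that filters change the genes tested and left-out tumours the samples. Genes and lists are counted here per comparison, so one named in more than 1 comparison counts in each. Over all alternatives the 18 gene results that passed kept their direction in 511 of 511 values and lost the call in 149. The 18 list results that were called gave 441 of 521 values with the same call, 73 without it and 7 reversed. The 114 gene results that did not pass gained a call in 72 of 3218 values and reversed in 2. Exoc7, BC018473, BC032265, E430014K09Rik and E430031D18Rik in homozygous KO, and E430014K09Rik, BC018473 and Meiob in heterozygous KO, kept their calls under every such alternative that gave a value for them. Each of these genes had 1 detected probe, so no second probe could check its call. The last 6 arrays alone, where only E430014K09Rik kept its call, are not counted among these alternatives.

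The count of 8 genes in homozygous KO tumours was 4 among probes detected on all 12 arrays, 5 with intercross wild-type alone as reference, 13 with an intensity trend and robust prior, and 13 with 12 arrays each as a sample. It was 120 with the tumours that stood apart left out, and 5 to 11 without single replicates. The count of 10 in heterozygous KO tumours was 6 with no detection filter, 0 among probes detected on all 12 arrays, and 5 in the 4-group model. It was 3 with intercross wild-type and 4 with control alone as reference, 19 with only the groups compared, and 4 with the array block. It was 99 with 12 arrays, 81 with the tumours that stood apart left out, 3 with control 1 and 2 as 1 sample, and 3 to 18 without single replicates. The count was 0 in both other comparisons under every alternative run.

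Sphk1 in homozygous KO turned from -0.01 to 0.35 with control alone as reference, 0.22 with the array block, 0.0238 with a linear term and 0.00048 with control 1 and 2 as 1 sample. It ran from -0.26 to 0.35 without single replicates. In heterozygous KO it turned from 0.27 to -0.0903 with intercross wild-type alone and -1.05 with the tumours that stood apart left out, and ran from -1.05 to 1.59. The 6 lists called in homozygous KO were 2 with intercross wild-type alone, 0 with an estimated correlation, 0 by fry, and 3 (without wild-type 2, control 2 or homozygous KO 3) to 9 (without wild-type 1). The 12 in heterozygous KO were 7 with the tumours that stood apart left out, 0 with an estimated correlation and 0 by fry. The correlation of effects, 0.66, was 0.48 and 0.49 with the reference split and 0.41 to 0.70 without single replicates. With the tumours that stood apart left out, Col1a2 in heterozygous KO was -0.66, and the medians of the lists were 0.0075 for epithelial-mesenchymal transition, -0.66 for fibroblasts and -0.85 for basal cells. Without single replicates these ran from -0.66 to 2.96, 0.0075 to 1.25, -0.66 to 1.76 and -0.85 to 2.08. The hypoxia list in heterozygous KO was -0.0799 with the array block.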

Other observations

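The genes and values here were picked after they were seen and were not tested. Some genes differed widely among the 6 SphK1 wild-type tumours. Acta1, skeletal muscle actin, was 13.65 on the log2 scale in control 3 and 11.29 in control 2 and at most 6.74 in the other 9 tumours. The muscle genes Myl1 (4.66 to 12.89) and Atp2a1 (5.11 to 12.45) were also highest in control 3. Wild-type 2 was highest in Cfd, the adipocyte protease adipsin (up to 12.51), Dcn, the matrix proteoglycan decorin (4.99 to 11.31), Ltf, lactoferrin (6.62 to 14.62), and the transcription factor gene Tfap2b (4.87 to 12.04). Control 1 was highest in the homeobox genes Hoxb2 (5.76 to 10.89) and Hoxb4 (4.97 to 9.83), and wild-type 3 in the protease gene Ctse (9.97 to 14.50). The milk protein gene Csn2 was 11.69 in wild-type 1 against 13.55 to 15.57 in the other 10 tumours. Krt14, a keratin of basal cells, was detected in none of the 3 tumours labelled homozygous KO, in 1 of the 2 labelled heterozygous KO and in 5 of the 6 wild-type tumours. The score of the whole basal list did not run alike in the 3. It was 1.03 in homozygous KO 2, above all wild-type tumours (at most 0.56), and -0.88 and -0.89 in homozygous KO 1 and 3.

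For 6 of the 8 transcripts that rose in tumours labelled homozygous KO, detected in every tumour of both KO groups, the size of the heterozygous difference was set against the homozygous one on the linear scale of normalised intensity. The excess over wild-type in heterozygous KO was 0.664 of that in homozygous KO for E430014K09Rik, 0.509 for Snhg16, 0.484 for BC018473, 0.465 for St6galnac2, 0.463 for E430031D18Rik and 0.416 for Exoc7. For E430014K09Rik and BC018473 the wild-type value taken off was background signal. The same holds for Meiob and BC032265, left out of the 6, whose ratios were 1.85 and 0.344. All these ratios come from 2 and 3 tumours and are given without an error. Of the clone-named transcripts, BC032265 was undetected in heterozygous KO and at least 1.22-fold higher in homozygous KO (limma adjusted p = 0.716). Homozygous minus heterozygous log2 differences were 0.76 for E430031D18Rik (SE 0.25), 1.03 for BC018473 (SE 0.52) and 0.59 for E430014K09Rik (SE 0.28), and none passed the test.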
